A study of Mus musculus with 2 samples.

How the data were processed

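The data were droplet single-cell RNA counts from cultured mouse bone marrow cells. Bone marrow enriched for stem and progenitor cells came from 5 C57BL/6 mice and was infected with a retrovirus carrying a short hairpin RNA (shRNA). Infected lineage-negative, Sca-1-positive, Kit-positive (LSK) cells, a fraction rich in blood stem and progenitor cells, were sorted by the GFP of the virus, per the series' design text, and grown for 3 days with GM-CSF and SCF at 10 ng/ml each in 20% serum, per the labels' protocols. One library came from cells with a control shRNA and 1 from cells with an shRNA against Cxxc5. Each library was a pool of 5 samples, so each group had 1 library and no replicate. Whether both pools came from the same mice was not clear from the sources used here.

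The deposited values are UMI counts per gene and cell barcode (counts of unique molecular identifiers, so that PCR copies of a molecule count once), made by the authors from 10x Genomics 3' version 2 libraries with Cell Ranger 2.1.1 on mm10, per the submitters' processing notes. The annotation release was not given in the sources used here. The matrices listed 28692 genes. Genes were located by Ensembl identifier in GENCODE M21, which uses GRCm38, the assembly that mm10 denotes. Of 570 genes in the lists fixed beforehand, 568 were matched by symbol, and Cebpd and Mx2 were not analysed here.

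Cells with at least 500 detected genes and at most 10% of UMIs from mitochondrially encoded genes were kept. This removed 13 of 2925 control and 11 of 6015 knockdown barcodes, all for their mitochondrial share. Scrublet, run on each library through scanpy 1.11.5, marked 8 control cells (0.275%) and 14 knockdown cells (0.233%), too few to rely on, and doublets were kept. As an alternative chosen after seeing this, the cells with the highest Scrublet scores were removed at a rate of 0.8% per 1000 cells, 68 control and 288 knockdown cells.

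Both libraries were clustered together without batch correction. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 exact nearest neighbours and Leiden resolution 0.6 were used. A cluster took the name of the marker list with most members among its top 10 genes by fold over all other cells, among genes of at least 50 CPM (UMIs of the gene over all UMIs, as counts per 1e6), if at least 3 of the list's markers were raised 1.5-fold at 20 CPM or more. Markers were fixed before the data were examined and this naming rule after. Ties and clusters without such markers stayed unnamed and are given by number, with their shares.

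Gene levels were UMI sums over cells divided by the library's total, as CPM, with exact Poisson intervals. Ratios are knockdown over control with exact intervals from the split of the UMIs, and shares of cells have exact Clopper-Pearson intervals. Where 0 cells held a UMI, the limit given is instead 3 cells over the number of cells, which is below the upper end of that interval. All intervals are 95% and cover counting error only, not differences between mice, infections or cultures. Those of gene levels, ratios and list medians treat UMIs as independent, so they also leave out the spread between cells. They are too narrow where few cells hold many of the UMIs. No p-value was computed. Genes were named by a rule of size fixed before the data were examined: Cxxc5, the 12 highest and 12 lowest ratios among genes of at least 20 CPM in a library, the 4 highest and 4 lowest in each class among genes of at least 50 CPM, up to 4 members of each fixed list, and the top genes of clusters. Members of fixed lists named within classes, and other genes outside this rule, were chosen after their values were seen. For 12 marker lists and 21 gene lists, the median log2 ratio over members of at least 10 CPM was set among 10000 random lists of the same size matched on mean expression. Members at least 1.2-fold apart are counted as higher or lower. Some lists share members, so their medians are not independent results. Classes and clusters with at least 100 cells in each library were compared. Cell cycle phases came from scanpy's scores after each cell was thinned to 5000 UMIs, which left out 115 control and 641 knockdown cells.

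The arithmetic was tested on simulated counts with 4659 genes, of which 200 were changed. The counts were drawn with counting error only, as the intervals assume, so coverage does not speak to spread between cells. Over all cells, planted folds of 2, 1.5, 0.667 and 0.5 gave median log2 estimates of 1.00, 0.57, -0.60 and -1.00. The limit first set for coverage was missed by the 1.5-fold genes and was replaced, after this was seen, by an exact binomial check against 95%. The intervals covered the planted value for 100%, 90%, 96% and 98% of the 50 genes at each fold and for 95.0% of the 4459 unchanged genes. A planted list of 15 genes lay at percentile 0 and 20 unchanged lists between percentiles 3.03 and 96.1. Genes of these lists and of the random lists were drawn independently. Members of the fixed lists can vary together between cultures, so their percentiles describe these libraries and do not measure chance. Shuffled ratios with a log2 shift of -0.1 planted on 1 3' UTR heptamer in 449 of 4652 genes returned it at rank 1. The heptamers ranked first in the data had mean shifts of -0.044 and 0.053, and recovery of shifts that small was not tested.

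Alternatives covered the filter on cells, doublets, the scaling of the libraries, the weighting of cells, depth, composition, minimum levels and the clustering. Sequences for 3' UTRs came from the longest annotated 3' UTR per gene in GENCODE M21, and genes without one of at least 50 bases were not searched. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.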

Results

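Single-cell transcriptomes were compared between mouse LSK cells carrying a control shRNA and LSK cells carrying an shRNA against Cxxc5, after 3 days in a culture that drives myeloid differentiation. Cxxc5 encodes a CXXC zinc finger protein known as a regulator of Wnt signalling. The control library held 2925 barcodes with 49333454 UMIs and the knockdown library 6015 barcodes with 62910229 UMIs. After filtering, 2912 control cells had a median of 17197 UMIs and 3480 genes, and 6004 knockdown cells a median of 10599 UMIs and 2755 genes. The median mitochondrial share was 3.92% and 3.98%. Cells held between 3618 and 46985 UMIs in the control and between 2136 and 33565 in the knockdown library. There was 1 pooled library per group, so no difference given here has a replicate check, and intervals cover counting error only.

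The first question was whether the targeted transcript was lower in the knockdown library. Cxxc5 (ENSMUSG00000046668, chromosome 18, 35829397 to 35861688, plus strand, GRCm38) had 462 UMIs or 9.38 CPM in the control library and 73 UMIs or 1.16 CPM in the knockdown library. The log2 ratio was -3.01, with a counting interval of -3.39 to -2.65. In the control library the transcript was most abundant in the dendritic cell-like cluster, at 42.0 CPM, and in unnamed cluster 6, where mast cell, basophil and multipotent progenitor markers were raised, at 34.5 CPM. The knockdown values there were 5.79 and 4.73 CPM. Cluster 1 had 11.97 and 1.17 CPM, and the granulocyte-monocyte progenitor-like cluster 4.92 and 0.75 CPM. In neutrophil-like cluster 3, 11 of 587 control cells held a Cxxc5 UMI and 0 of 968 knockdown cells, which allows a share of up to 0.310%. A Cxxc5 UMI was found in 12.6% of control cells (11.5 to 13.9%) and 1.22% of knockdown cells (0.954 to 1.53%). At 5000 UMIs per cell the shares were 4.54% and 0.578%, leaving out 115 control and 641 knockdown cells. No cell type known to lack Cxxc5 was at hand as background, and the nearest to it was neutrophil-like cluster 7, with 0 of 170 control and 0 of 173 knockdown cells. These counts allow shares of up to 1.76% and 1.73% at median depths of 9090.5 and 6210.0 UMIs. The 968 knockdown cells of cluster 3, at a median of 9365.5 UMIs, gave a tighter limit, and the knockdown share of 1.22% over all cells was above it.

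**Figure D1:**
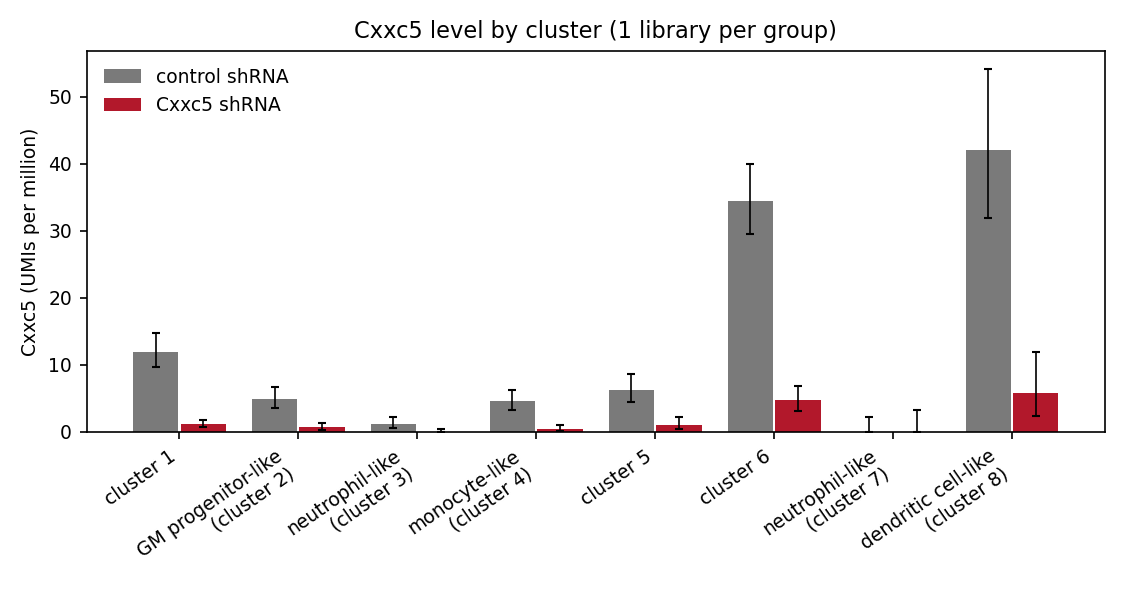
Cxxc5 level in CPM for the 8 clusters with at least 100 cells in each library, control shRNA in grey and Cxxc5 shRNA in red, 1 library each, with exact 95% Poisson intervals. The control level was highest in the dendritic cell-like cluster (42.0) and cluster 6 (34.5), where the knockdown library had 5.79 and 4.73.

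The next question was which cell classes the cultures held. Genes named as leading a cluster are among its top 10 by fold and not always the first. Neutrophil-like cells were fewer in the knockdown library, 19.0% (18.0 to 20.0%) against 26.0% (24.4 to 27.6%) in the control library. Most of them were in cluster 3, led by Stfa1, Fcnb, S100a9 and Ngp, at 20.2% and 16.1%. The later neutrophil-like cluster 7, led by Ltf, Camp, Lcn2 and Ly6g, made up 5.84% of control and 2.88% of knockdown cells. Granulocyte-monocyte progenitor-like cells, led by Nkg7, Ctsg, Prss57 and Elane, were more frequent in the knockdown library, 19.3% (18.3 to 20.3%) against 13.8% (12.6 to 15.1%). This name separates the cells only weakly. Nkg7 was 2.01-fold and Elane 1.76-fold above other cells. The progenitor markers Elane, Nkg7, Igsf6 and Clec12a were also raised in neutrophil-like cluster 3. Cluster 1 stayed unnamed. Its leading genes Cited4, Fkbp11, Rangrf and Mybbp1a were at most 1.97-fold above other cells, and it held 10.9% of control and 21.5% of knockdown cells. Its median UMI counts were 1.36 and 1.16 of those of its library. Alternative clusterings were read for named classes only, so this share was not checked against depth, doublets or cluster borders. Cited4 was also higher in the knockdown library in other clusters, but the cluster's top 10 genes had a median log2 ratio of 0.08 within it. Whether the difference in share comes from the library or from a cell type was not tested. Monocyte-macrophage-like cells, led by Lpl, Irf8, Ms4a6c and Ccr2, made up 16.0% and 13.2%.

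The remaining clusters were smaller or unnamed. Cluster 6 expressed Prss34, Gata2, Pf4 and Cpa3, and mast cell and basophil markers tied in its leading genes. It held 12.5% of control and 10.7% of knockdown cells. Cluster 5, led by Slc39a1, Rpgrip1 and Actb, held 16.1% and 12.9%, and its median UMI counts were 0.531 and 0.646 of those of its library. Cluster 9, led by the p53 targets Phlda3, Cdkn1a and Ccng1, held 0.549% and 0.550%. Together the unnamed clusters held 40.1% of control and 45.6% of knockdown cells. The dendritic cell-like cluster, led by Cd74, Ccl17 and H2-Aa, held 3.74% and 2.63%, and its size was not compared because its defining genes differed within it between the libraries, by a median log2 ratio of -0.88. Mast cell-like cluster 10, led by Cma1, Mcpt2 and Tpsb2, had 10 control and 19 knockdown cells.

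Class sizes depended on how cells were clustered. The defining genes of the neutrophil-like clusters also differed within them, by a median log2 ratio of 0.30. When each library was clustered alone, the neutrophil-like share was 14.6% in the control and 20.4% in the knockdown library, the opposite order, the progenitor-like shares were 27.2% and 26.3%, and the monocyte-macrophage-like shares 14.2% and 15.8%, both also in the opposite order. Without called doublets the progenitor-like shares were 14.1% and 14.8%. When 289 genes that differed between the libraries were left out, a choice made after seeing the data, the neutrophil-like shares were 15.4% and 9.63% and the progenitor-like shares 12.7% and 20.4%.

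**Figure D2:**
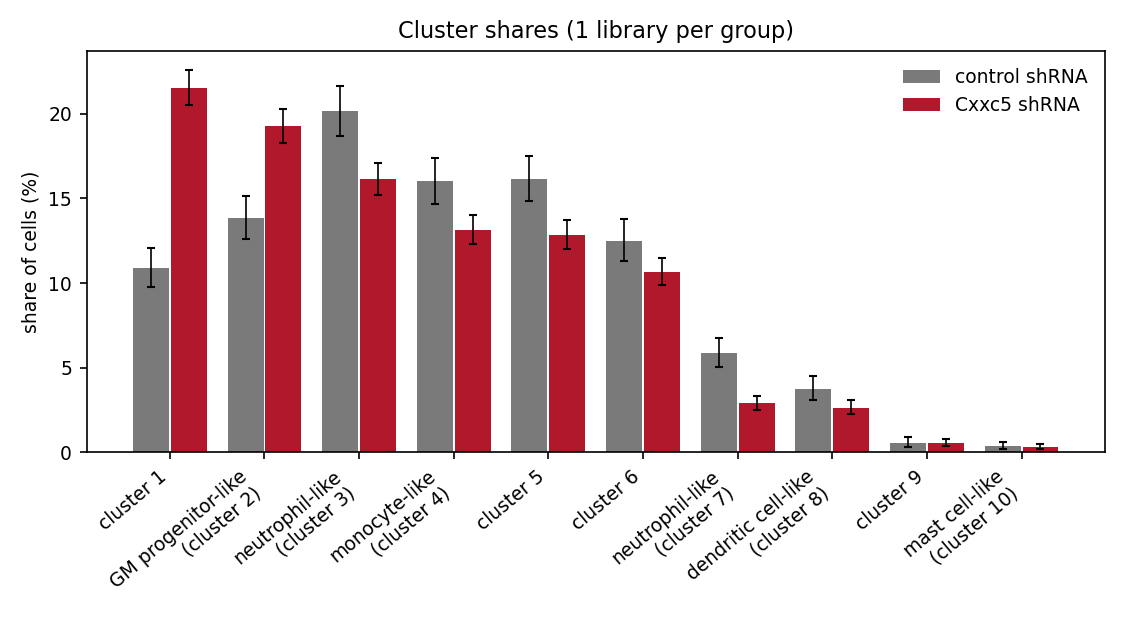
Share of cells in each of the 10 clusters of the joint clustering, control shRNA in grey (2912 cells) and Cxxc5 shRNA in red (6004 cells), with exact 95% binomial intervals. Cluster 1 held 10.9% of control and 21.5% of knockdown cells, and both neutrophil-like clusters had lower knockdown bars, an order that turned when each library was clustered alone.

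Gene levels were then compared over all cells. Among 4798 genes of at least 20 CPM, log2 ratios had a median of 0.04, and 5th and 95th percentiles of -0.24 and 0.22, so 92.9% of genes were within 1.2-fold. The highest ratio was that of Naf1, an assembly factor of box H/ACA ribonucleoproteins, at 14.5 CPM in the control and 35.7 CPM in the knockdown library (log2 1.30, interval 1.18 to 1.43). Bcat1, a branched-chain amino acid transaminase, had 9.44 and 20.9 CPM (1.15), and Tmem55a 16.9 and 34.2 CPM (1.02). Cited4 (0.82), Klhl5 (0.79), Nsmce2 (0.78), Rnf14 (0.77), Man2a1 (0.77), Suclg2 (0.70), Smim11 (0.68), D15Ertd621e (0.64) and Chst13 (0.58) followed. Of these 12 genes, 9 were higher in the knockdown library in each of the 8 clusters compared. Naf1 lies on chromosome 8 (66860217 to 66890564), Bcat1 on chromosome 6 (144993835 to 145076184) and Tmem55a on chromosome 4 (14864076 to 14915176).

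The lowest ratios were those of Prss34, a basophil protease (26.2 and 7.73 CPM, log2 -1.76), Cd74, the MHC class II invariant chain (99.9 and 33.1 CPM, -1.59), and S100a4, a calcium-binding protein (77.1 and 28.9 CPM, -1.42). H2-Aa had a log2 ratio of -1.41 and H2-Ab1 of -0.98, and the dendritic cell chemokine gene Ccl17 of -1.26. The class II genes were not lower in every cluster. Cd74 was lower in 6 and higher in 2 clusters, H2-Aa lower in 2 and higher in 3, and H2-Ab1 lower in 3 and higher in 5, while dendritic cell-like cells held 1447 of the 1486 control and 667 of the 716 knockdown UMIs of H2-Aa, and 1222 of 1465 and 580 of 950 of H2-Ab1. Thbs1, which encodes the matrix protein thrombospondin-1, had 80.1 and 33.8 CPM (-1.24), Haus4, a subunit of the augmin complex of the spindle, 55.7 and 24.2 CPM (-1.20), and Myl10 276 and 127 CPM (-1.13). Lgals3 (-1.06), Klf2 (-1.04) and Bcl2a1a (-1.01) completed the 12. S100a4, Thbs1, Haus4 and Lgals3 were lower in each of the 8 clusters. Thbs1 lies on chromosome 2 (118111876 to 118127133), Haus4 on chromosome 14 (54541785 to 54554616) and S100a4 on chromosome 3 (90603771 to 90606045). With cluster shares held at those of the control library, the log2 ratios of Cd74, H2-Aa, Ccl17, Lgals3, Klf2 and Bcl2a1a were -1.05, -0.87, -0.69, -0.64, -0.69 and -0.63. Prss34 rested on few cells, since 86.1% of its control UMIs were in 10 cells, and its log2 ratio was -1.37 without the 10 cells richest in it in each library and -2.92 in thinned cells. H2 genes and Bcl2a1a belong to families of similar genes, so their counts are uncertain.

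Genes of antigen presentation and of monocytes were lower. All 8 measured genes of MHC class II presentation were lower in the knockdown library (median log2 -1.10, percentile 0 of matched random lists), among them Cd74, H2-Eb1 (-1.45) and H2-DMb2 (-1.22). All 5 dendritic cell markers were lower (-1.41, percentile 0). Of these, Cd74, H2-Aa, H2-Ab1 and H2-Eb1 are also in the class II list, so this is not a separate result. Of 12 monocyte-macrophage markers, 10 were at least 1.2-fold lower (-0.51, percentile 0), with Csf1r at 10.7 and 5.36 CPM, Ccr2 at -0.82 and Lyz2 at -0.74. With control cluster shares the medians were -0.27 for monocyte-macrophage and -0.87 for dendritic cell markers. Of 16 monocyte-macrophage effector genes, 6 were lower and 2 higher (-0.19, percentile 0), and the median was -0.07 at a minimum of 50 CPM. All 4 measured inflammatory cytokine and chemokine genes were lower (-0.66, percentile 0). Ccl17, also among the dendritic cell markers, was at -1.26, Ccl6 at -0.76, Ccl9 at -0.55 and Nfkbia at -0.48.

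Late neutrophil genes were also lower over all cells. Of 15 secondary and tertiary granule genes, 9 were lower and 0 higher (-0.40, percentile 0), with Chil3 at -0.82, Cybb at -0.56 and Hp at -0.51, and 5 of 14 neutrophil markers were lower (-0.22, percentile 0). Most of these markers are also in that granule list. With cluster shares held at those of the control library, both medians had the other sign, 0.10 for granule genes and 0.21 for neutrophil markers. Primary granule genes, expressed earlier in the lineage, had a median of 0.07 (percentile 89.6), with Mpo at 0.27, Ctsg at 0.21 and Serpinb1a at -0.37. Granulocyte-monocyte progenitor markers also had a median of 0.07 (percentile 85.6), and share Mpo, Elane, Prtn3, Ctsg, Ms4a3 and Cst7 with the primary granule list. Multipotent progenitor markers (4 measured) had a median of -0.11 (percentile 4.97).

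**Figure D3:**
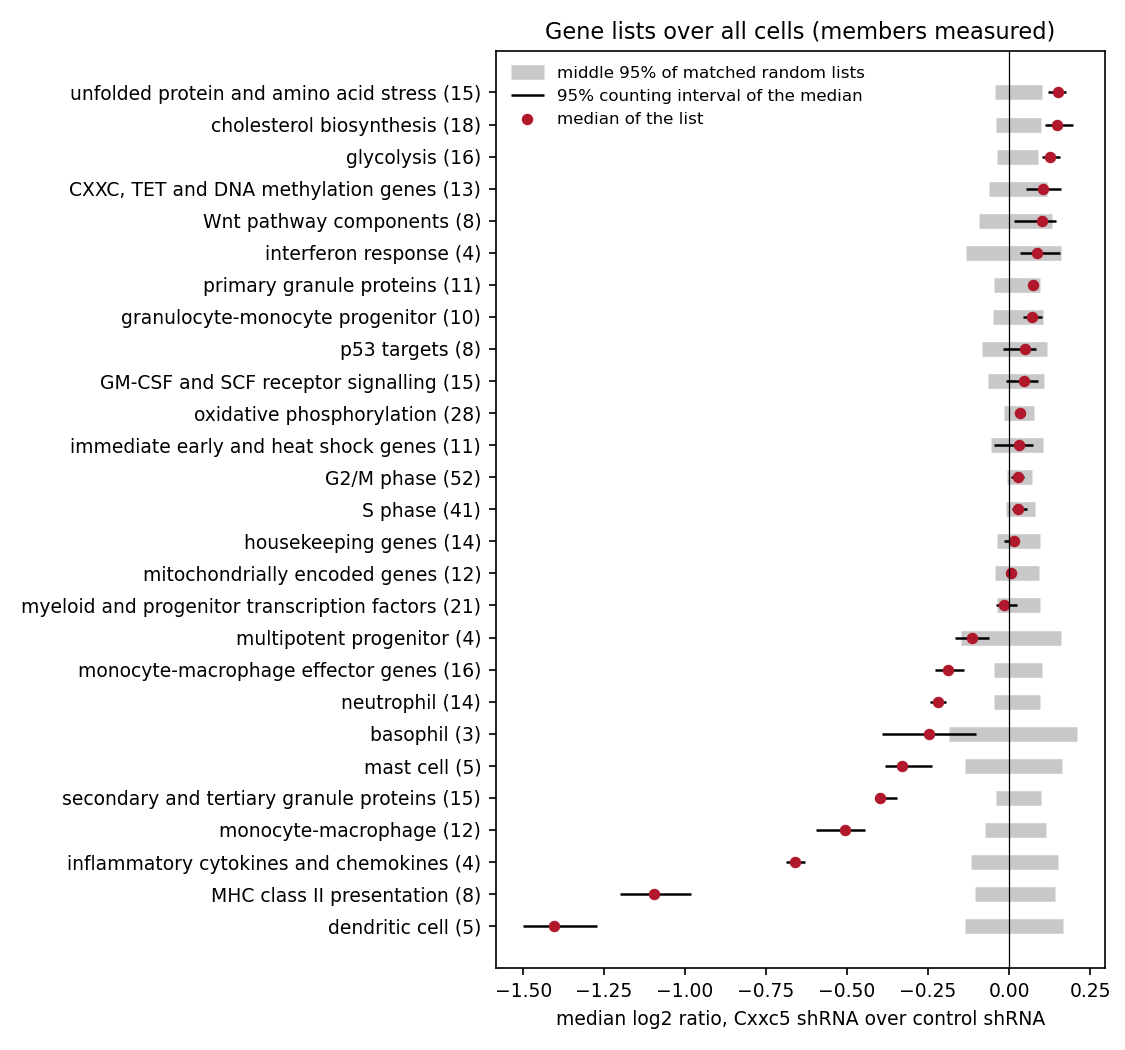
Median log2 ratio of knockdown over control for 27 gene lists with at least 3 measured members, over all cells of 1 library per group. Red points are medians, black lines their 95% counting intervals and grey bars the middle 95% of 10000 matched random lists. MHC class II presentation (-1.10), inflammatory genes (-0.66) and monocyte-macrophage markers (-0.51) lay left of their bars, and cholesterol biosynthesis (0.15) right of its bar.

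Metabolic lists had medians slightly above those of random lists. Unfolded protein and amino acid stress genes had a median of 0.15 (percentile 99.95), with Hyou1 at 0.38 and Hspa5, an endoplasmic reticulum chaperone, at 0.28, and of 0.08 with control cluster shares. Cholesterol biosynthesis genes had a median of 0.15 (percentile 99.97), with Idi1 at 0.32 and Cyp51 at 0.27. Glycolysis genes had a median of 0.13 (percentile 99.9), with the lactate transporter gene Slc16a3 at 0.41 and Tpi1 at 0.35. Only 2 of 18 cholesterol, 2 of 15 stress and 3 of 16 glycolysis genes were 1.2-fold higher. The oxidative phosphorylation list had a median of 0.03 (percentile 54.1), although its member Cycs was at -0.85, a gene with processed copies whose counts are uncertain.

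Lists tied to the known roles of Cxxc5 differed little. The 8 measured Wnt pathway components had a median of 0.10 (percentile 91.3), all within 1.2-fold, with Ctnnb1 at 0.18 and Gsk3b at -0.19. Only 2 of 18 Wnt targets reached 10 CPM, Cd44 at 0.20 and Myc at 0.04. The 13 CXXC, TET and DNA methylation genes were all within 1.2-fold (median 0.11, percentile 95.7), with Kdm2b at 0.24 and Dnmt3a at 0.23. GM-CSF and SCF receptor signalling had a median of 0.05 (percentile 69.5), with Spred1 at 0.63 and Csf2rb at -0.28, and myeloid and progenitor transcription factors -0.02 (percentile 7.98), with Klf4 at -0.73 and Irf8 at -0.46. The medians of interferon response (0.09, percentile 81.1), p53 target (0.05, percentile 69.3), immediate early and heat shock (0.03, percentile 54.5), S phase (0.03, percentile 31.7), G2/M phase (0.03, percentile 40.3), mitochondrially encoded (0.01, percentile 30.4) and housekeeping genes (0.01, percentile 32.9) stood inside the range of random lists. Mast cell markers had a median of -0.33 (percentile 0.07), which was -0.08 with control cluster shares, although Cma1 had 9.17 CPM in the control and 18.4 CPM in the knockdown library, and the 3 basophil markers -0.25 (percentile 0.92), which was 0.25 at a minimum of 50 CPM, where only Mcpt8 was left. Fewer than 3 members were measured for megakaryocyte (Pf4, -0.23), erythroid (Hbb-bt, -2.05, and Blvrb, -0.50), lymphoid (Cd79b, 0.02) and stromal markers (Pecam1, -0.22), and none for eosinophil markers.

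Within neutrophil-like cells (757 control, 1141 knockdown), secondary and tertiary granule genes had a median of -0.00 (percentile 46.8), but single members went both ways, with Ltf at 0.64, Ngp at 0.25, Chil3 at -0.37 and Hp at -0.36. Neutrophil markers had a median of 0.13 (percentile 99.8). Nsmce2 (log2 1.27), Smim11 (1.01), Chil1 (0.86) and Orm1 (0.86) had the highest ratios. Thbs1 had 55.6 CPM in the control and 10.05 CPM in the knockdown library (-2.47), and Cycs (-1.43), Ccl9 (-1.38) and Myl10 (-1.20) were also among the lowest. Of the 4 measured inflammatory genes 3 were lower (median -1.21, percentile 0), with Il1rn at -1.66. Cluster 3 held most of the class in both libraries, but the later cluster 7 gave 170 of 757 control and 173 of 1141 knockdown cells. The class medians thus mix levels inside clusters with this difference in make-up. Inside cluster 3 and inside cluster 7, the top 10 genes of the cluster had a median log2 ratio of 0.30.

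Within monocyte-macrophage-like cells (466 and 790), 7 of 12 monocyte-macrophage markers were at least 1.2-fold lower and 0 higher in the knockdown library (median -0.33, percentile 0), with Lyz2 at -0.78, Ccr2 at -0.72 and Csf1r at -0.65. Neutrophil markers (6 of 9 lower, median -0.57, percentile 0) and secondary and tertiary granule genes (10 of 12 lower, -0.53, percentile 0) were lower still, so lower summed values in this class were not limited to monocyte genes. Cited4 (0.65), Scd2 (0.59), Smim11 (0.52) and Ccnd2 (0.45) had the highest ratios there, and Ngp (-1.19), Chil3 (-1.14), S100a4 (-1.07) and Myl10 (-1.01) the lowest. Of 5 measured MHC class II presentation genes, 4 were at least 1.2-fold lower (median -0.53, percentile 0.02). Ngp came mainly from few cells, with 77.1% of its control UMIs in 10 cells. Of the S100a8, S100a9 and Ngp UMIs together, 10 cells held 66.3% in the control and 39.8% in the knockdown library. The lower neutrophil and granule lists thus may not describe the class as a whole.

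Within granulocyte-monocyte progenitor-like cells (403 and 1158), primary granule genes had a median of 0.02 (percentile 70.1), with Prtn3 at 0.14 and Serpinb1a at -0.35. Unlike over all cells, neutrophil markers (median 0.19, percentile 99.98) and secondary and tertiary granule genes (0.12, percentile 99.7) had medians above 0, with 3 of 11 and 3 of 13 members higher. Chil3, in both lists, at -0.69 and the granule gene Hp at -0.55 went the other way. Monocyte-macrophage markers had a median of -0.27 (percentile 0.43). BC100530 (1.48), Lipg (0.89), Stfa1 (0.82) and Thy1 (0.74) had the highest ratios, and Thbs1 (-1.52), Haus4 (-1.49), Myl10 (-1.18) and Cycs (-1.13) the lowest. BC100530 and Stfa1 belong to the stefin A family, whose near-identical members share reads.

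Within dendritic cell-like cells (109 and 158), 9 of 10 MHC class II presentation genes were lower (median -0.88, percentile 0), with Cd74 at 3367 and 1615 CPM. This class was mixed. Granulocyte-monocyte progenitor markers (7 of 10 higher, median 0.49, percentile 100) and primary granule genes (0.28, percentile 100) were higher in it in the knockdown library. Cells with at least 10 UMIs of Cd74, H2-Aa, H2-Ab1 and H2-Eb1 together, a limit set after seeing the data, were 59 of the 109 control and 52 of the 158 knockdown cells. Over all classes such cells made up 2.13% (1.64 to 2.72%) of control and 0.983% (0.749 to 1.27%) of knockdown cells. At 5000 UMIs per cell the shares were 1.75% and 0.783%. The median level of these genes per such cell of the class, cells chosen by the same genes, was 7948 and 7663 CPM. A fixed limit in UMIs asks for a higher level in the library of lower depth. At 5000 UMIs per cell the median was 7600 and 7900 CPM, the other order, and the summed level 10898 and 8580 CPM. Summed over these cells without thinning, Cd74 was at -0.47 (-0.55 to -0.39), H2-Eb1 at -0.32 and H2-Aa at -0.31. With limits of 5 and 20 UMIs, 65 and 57, and 56 and 46, cells of the class passed. The highest ratios in the class, of Ngp (3.85), S100a9 (3.07), Lcn2 (2.85) and S100a8 (2.70), rested on few cells, with 93.6% of the knockdown S100a8 UMIs in 10 cells. Ccl22 had 317 UMIs in 6 control cells and 23 UMIs in 2 knockdown cells. Ccl6 (-2.09), Bcl2a1a (-1.63) and Bcl2a1d (-1.52) were also among the lowest.

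In the unnamed clusters, Thbs1 was at -1.38 in cluster 1 and -1.35 in cluster 5, Haus4 at -1.39 and -1.32, Myl10 at -1.03 and -1.15, and Rnf5 at -0.96 and -0.95. Mt2 (0.77), Cited4 (0.70), Wfdc21 (0.56) and Smim11 (0.53) had the highest ratios in cluster 1, and Cited4 (0.65), Scd2 (0.58), Slc16a3 (0.55) and Smim11 (0.55) in cluster 5. In cluster 6, Suclg2 (0.74), Klhl5 (0.72), Smim11 (0.65) and Ywhag (0.62) were highest. Its lowest ratios were carried by few cells. Prg2 had 307 UMIs in 1 control cell and 14 UMIs in 4 knockdown cells. Hbb-bt was at -1.95, with 86.6% of its control UMIs in 10 cells, while its paralogue Hbb-bs was at 3.31. Fcer1a was at -1.65 and Prss34 at -1.53, the last with 1269 UMIs in 32 control and 479 UMIs in 34 knockdown cells.

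The last comparison was of cell cycle phases. At 5000 UMIs per cell, 9.69% (8.62 to 10.9%) of control and 5.35% (4.76 to 5.99%) of knockdown cells were scored as G1, 38.1% and 37.4% as S, and 52.2% (50.3 to 54.0%) and 57.3% (55.9 to 58.6%) as G2/M. Without thinning the G1 shares were 5.43% and 3.43%, the S shares 35.3% and 32.3%, and the G2/M shares 59.3% and 64.3%. Cluster 6 differed most among the clusters compared, with 21.1% of control and 9.40% of knockdown cells in G1. Thinning kept 337 of its 364 control and 521 of its 640 knockdown cells, so cells of low depth were left out unequally. In granulocyte-monocyte progenitor-like cells the G1 shares were 6.22% and 5.24%. These scores are calls from transcripts relative to the cells in hand, do not measure division, and can carry free RNA.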

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

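Alternatives that removed the highest doublet scores, left out differing genes or cells with neutrophil transcripts, or left out the 10 cells richest in a gene were chosen after seeing the data. The Cxxc5 ratio moved less than its counting interval in all 6 alternatives, and the 12 highest and 12 lowest genes kept their sign in every alternative run, with 160 values inside the counting interval and 32 outside it. Of the list medians, 155 stayed within their interval and 58 did not, and 3 reversed. The spread between the 5th and 95th percentiles of log2 ratios, 0.46, was 0.52 with per-cell means, 0.40 with weighting to the control composition, 0.58 with thinned cells, 1.68 with no minimum level and 0.44 with a minimum of 50 CPM. The causes of the changes listed here were not tested, except that weighting to the control composition removes shifts in cluster shares and a lower minimum adds genes with few UMIs. Composition weighting, with the minimum of 10 CPM applied to the weighted levels, so that list members could differ from those in the report, gave list medians of 0.16 for neutrophil markers and 0.10 for secondary and tertiary granule genes, both reversed, -0.24 for monocyte-macrophage markers, 0.016 for primary granule genes and -0.77 for MHC class II presentation. Basophil markers reversed to 0.25 at a minimum of 50 CPM, where only Mcpt8 was left. MHC class II presentation was at -1.20 with no minimum and -1.59 at 50 CPM, where only Cd74 was left. With median-of-ratios scaling, per-cell means and thinned cells, primary granule genes were at 0.054, 0.13 and 0.15, and secondary and tertiary granule genes at -0.42, -0.47 and -0.52. Clustering each library alone reversed the difference (knockdown minus control, in points) to 5.77 for neutrophil-like, 1.59 for monocyte-macrophage-like and -0.93 for progenitor-like cells. The neutrophil-like difference was -5.03 with all barcodes. The progenitor-like difference was 2.44 without cell cycle genes, 8.85 with thinned cells, 0.67 without called doublets, 1.51 with all barcodes and 7.68 without differing genes. The monocyte-macrophage-like difference was -0.65 without cell cycle genes, -4.94 without called doublets and -0.53 without the highest doublet scores, and the class was not found at resolution 0.3 or without differing genes. The dendritic cell-like difference was -4.78 and -2.53 at resolutions 0.3 and 1.2, -2.40 without cell cycle genes, -2.49 without the highest doublet scores and -4.88 without differing genes, but at resolution 0.3 and without differing genes the class was a wider one, with 17.9% and 16.1% of control cells. Clustering again without the 8 control and 14 knockdown cells called as doublets moved shares by several points. Within neutrophil-like cells the median of secondary and tertiary granule genes, -0.00, was -0.0097, -0.10 and 0.018 with median-of-ratios scaling, per-cell means and the highest doublet scores removed. Without thinning the G1 difference was -1.99 points and the S difference -3.02. Depth limits the comparison of single cells, since the knockdown median was 0.616 of the control median. No paired analysis was possible because each group had 1 library.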

Other observations

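The heptamer scan, the doublet tests and the pool comparison for class shares, and for MHC class II the tests on class size, on cells with high levels and without the richest cells, and the floor for a median of 0, were chosen after the results were seen. Some genes had 1 direction in every cluster, by varying amounts. Thbs1, S100a4, Haus4 and Lgals3 were lower, and Naf1, Tmem55a, Klhl5, Nsmce2, Rnf14, Man2a1, Suclg2, Smim11 and D15Ertd621e higher, in the knockdown library in each of the 8 clusters compared. The log2 ratio of Thbs1 ranged over clusters from -2.57 to -0.44, that of Lgals3, a macrophage effector gene, from -0.94 to -0.16 and that of Naf1 from 0.87 to 1.52. Among 3' UTR heptamers, a scan that included these genes found that 7 of the 12 genes with the highest ratios carried GTACATT (Naf1, Tmem55a, Klhl5, Rnf14, Man2a1, Suclg2 and D15Ertd621e), against 10.4% of the 4652 genes searched and 0 of the 12 lowest. These counts were not matched on 3' UTR length. The 7 carriers had 3' UTRs of 1049 to 2811 bases. The 12 lowest had 144 to 740 bases, apart from Thbs1 with 2107, so the 0 there says little. GTACATT ranked first of 15955 heptamers for high ratios in the length-adjusted scan, with a score of 8.50, where 1 shuffle of the ratios reached 3.51. Genes with the octamer GTACATTA had a median composition-weighted log2 ratio of 0.10 (82 genes), those with GTACATT only 0.024, those with TACATTA only 0.0017, those with a shared hexamer 0.0048 and those with no match 0.0085.

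CAAATTC ranked first for low ratios, with a score of -6.63 against -4.08 in the same shuffle. The median log2 ratio was -0.05 for 159 genes with the octamer CAAATTCA, -0.02 with CAAATTC only, -0.01 with AAATTCA only and 0.02 with none. CAAATTCA occurs once in the transcript Cxxc5-201, at position 1212 of 2302 and before its 3' UTR, and 15.2% of the scanned heptamers occur in a Cxxc5 transcript. Of the 12 genes with the lowest ratios, only S100a4 carried CAAATTC, and of the 12 highest only Bcat1, against 9.14% of all genes searched. These counts were not matched on 3' UTR length either.

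For genes with 1 direction in every cluster, a fit on 3' UTR length and GC content neither supports nor excludes these as causes. It explained almost nothing (r squared 0.00227). It was read on 23 of the named genes with the highest and lowest ratios, not all of which had 1 direction in every cluster. Their median absolute composition-weighted log2 ratio was 0.72 before and 0.73 after. In 3450 held-out genes of 5 to 20 CPM, genes with GTACATT were 0.038 above the others in median log2 ratio, above all 10000 sets matched on 3' UTR length, so a candidate explanation for part of the higher genes is repression by the control hairpin through its seed. By cluster, among genes that include those scanned, this difference was 0.038 to 0.062 in clusters 1, 2, 4, 6 and 8, but 0.013 in cluster 5 and 0.0028 and -0.00038 in neutrophil-like clusters 3 and 7, so the cause of the higher genes stays open there. Genes with CAAATTC were -0.013 from the others in held-out genes, at percentile 2.78, which missed the limit of 2.5 set beforehand, and by cluster, with scanned genes included, lower in all 8, from -0.0095 in cluster 4 to -0.064 and -0.13 in clusters 3 and 7, which leaves the seed of the Cxxc5 hairpin open. Neither hairpin sequence was among the sources used here, and effects of Cxxc5 loss were not tested apart from those of the hairpins.

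For fewer neutrophil-like and more progenitor-like cells, depth as the cause was argued against by clustering cells thinned to 5000 UMIs. This left the neutrophil-like difference at -6.85 points. Removing the highest doublet scores left -7.64 points, and removing the called doublets -5.57 points. These removals cannot decide on doublets, because the cells were clustered again and the Scrublet calls were too few to rely on. For the progenitor-like difference, thinning and removing the highest scores gave 8.85 and 6.79 points, but clustering again without the called doublets gave 0.67. Only 0% of control and 0.173% of knockdown cells of that cluster were called, too few to remove the difference by themselves. That setting shows that the share depends on the clustering. It cannot decide on doublets, which stay open for the neutrophil-like and the progenitor-like part. A difference between the mouse pools or infections cannot be told apart from the knockdown, with 1 library per group, and clustering each library alone gave 5.77 points in the other direction, so the shift may also reflect where cluster borders fall. An effect of Cxxc5 loss stays among the open explanations, untested.

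For lower MHC class II transcripts, a smaller dendritic cell-like class alone was argued against by the median of -0.88 within the class. But the class is a mixture in which progenitor markers were higher (median 0.49), so fewer dendritic cells and more progenitor-like cells within it are not excluded. Only 5 of 109 control and 5 of 158 knockdown cells of the class carried 10 or more S100a8, S100a9 and Ngp UMIs. Leaving out so few cells could move the median little, and it was -0.94 without them. Their small number, not this test, argues against dilution by them. The median Cd74 level per cell of the class was 1019 CPM in the control library and 0 in the knockdown library. This is a log2 ratio of at most -1.21 with the latter set to 3 UMIs at its median depth. It cannot decide whether a few very high cells were the cause, because the class is a mixture. In it, 44 of 109 control and 101 of 158 knockdown cells held fewer than 5 UMIs of Cd74, H2-Aa, H2-Ab1 and H2-Eb1. Without the 10 richest cells of each library the list median within the class was -0.83 (counting interval -0.93 to -0.67). The difference thus did not rest on those cells alone, although they were chosen by genes compared. Among class cells with at least 10 UMIs of Cd74, H2-Aa, H2-Ab1 and H2-Eb1 the log2 ratio of median levels was -0.053. At 5000 UMIs per cell the medians had the other order, 7600 CPM in the control and 7900 CPM in the knockdown library. These cells were chosen by the genes compared, so fewer cells with high levels and a lower level per cell cannot be told apart. Summed over those cells without thinning, H2-DMb2 was at -0.61, Ctss at -0.55, Cd74 at -0.47 and H2-DMb1 at 0.25. Pool differences were not tested, and an effect of Cxxc5 loss stays open.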
